A study of Arabidopsis thaliana with 92 samples.

How the data were processed

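The data were 92 one-colour arrays of RNA from leaves of 4-week-old Arabidopsis thaliana plants, taken 24 h after the leaves were infiltrated. Per the labels, 77 arrays followed infiltration with Pseudomonas syringae pv. maculicola ES4326 (Psm), 6 followed its COR(-) strain, which makes no coronatine, and 9 followed water. The inoculum was 1e+08 colony-forming units per ml. The arrays belong to 4 experiments (LW01, LW02, LW03 and LW05), each with 3 sets that the labels number, and cover 22 genotypes including Col-0. Each group of genotype, treatment and experiment had 3 arrays, except pbs3 with 2. The series' design text describes the sets as biological replicates and each sample as leaves pooled over pots.

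Per the labels' protocols, total RNA was amplified, labelled with Alexa555 and hybridised to 1-colour arrays. The deposited table holds 1 value for each of 576 features and each array. The deposited values were taken as log2 of the authors' array signal, a base inferred from their range of -0.741 to 14.4, with array medians from 3.605 to 4.867. The scanner, the background correction and the normalization between arrays are not given in the sources used here. The array medians averaged 3.87 ± 0.195 (SD, n = 9) after water, 4.27 ± 0.125 (SD, n = 6) after the COR(-) strain and 4.64 ± 0.135 (SD, n = 77) after Psm, so the deposited values had not been brought to 1 median. No signal over background was used here, so the precision that can be given rests on the number of arrays and the spread of each feature.

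The platform table names 181 features by exactly 1 gene, and 180 of these were found in the gene table by Entrez ID. A symbol other than the locus code was given for 48. The other 395 features entered every test but are counted without a name. No genome build is named in the sources, so no coordinates are given.

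All arrays entered 1 linear model in limma 3.58.1 (R 4.3.3) with a coefficient for each of the 31 groups. Each of 38 comparisons was a contrast of these coefficients with empirical Bayes moderation and Benjamini-Hochberg adjustment over the 576 features, and a feature was called at an adjusted p under 0.05. Every value labelled SE or adjusted p comes from that model unless another setting is named. Comparisons stay inside an experiment. The infection response in Col-0 averages LW03 and LW05, the genotype effect of coi1 averages LW02 and LW05, and eds1 minus pad4 sets 2 differences from Col-0, in LW03 and in LW01, against each other.

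The named genes follow a rule written before the data were examined. It takes the named features past the threshold that change in the same direction in every set, the 10 largest per direction for infection in Col-0, coronatine in Col-0 and the coi1 genotype, and the 4 largest per direction elsewhere. It also takes members of 19 gene lists that hold 234 genes. Named features measured 9 of these genes, and a single list had at least 3 measured members and was tested as a group: salicylic acid (SA)-responsive and systemic acquired resistance genes, with WRKY53, GRX480 and UGT76B1. The others measured were PDF1.2 (ethylene and jasmonate (JA)/ethylene defence), AT2G04400 (tryptophan and camalexin), WRKY22 and WRKY29 (pattern-triggered immunity), GRX480 again (detoxification and redox), and AT4G26410 and AT5G60390 (reference genes). None of the 15 genes of the list of mutated genes had a named feature, and neither had the cell type markers, so these were not analysed here. The group was tested with limma's fry, and with camera and an estimated correlation as the alternative. The p-values of both tests are given without adjustment over the 38 comparisons.

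The labels give the sets a meaning shared by all genotypes of an experiment, so the set numbers pair the arrays. This was checked by correlating deviations from the group means. Arrays of the same set had a mean r of 0.423, 0.362, 0.3 and 0.406 in LW01, LW02, LW03 and LW05, against -0.207, -0.18, -0.141 and -0.2 for arrays of different sets. Deviations cancel within a group, so the negative values follow from the positive ones and add no separate evidence. The model leaves the set out, as fixed before the data were examined. The fit with the set as a replicate block is given beside a value in the report whose call it changed and a count that it moved by over 1.5 times, as for the 8 calls of the coronatine by coi1 interaction, which became 27.

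Other alternatives fixed in advance were centring each array on its median or on AT4G26410 and AT5G60390, quantile normalization, leaving out the dimmest 25% of features, array quality weights, a minimum change of 2-fold, a model with the arrays of the experiments in the contrast alone, and leaving out each array in turn. Fits without the Col-0 water array of LW05 set 1 in every comparison were added after the data were seen. No 2 arrays held the same values.

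The model was tested on simulated data made from the real means and spreads of the 576 features, with seeded changes of 1.5-, 2- and 4-fold. For the infection response in Col-0, 43.3%, 76.1% and 98.5% of the changed features were recovered at these sizes. The shares were 19.4%, 50.7% and 86.4% for the sid2 comparison, 13.4%, 58.2% and 93.9% for pbs3, and 10.4%, 29.9% and 74.2% for the coronatine by coi1 interaction. Between 3 and 5 of 376 unchanged features were called, and no changed feature was called in the wrong direction. The noise was drawn independently for each feature and array. It lacked the set effects and the shifts between treatments of the real arrays, so these shares may not apply to the real data.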

Results

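The arrays measured 576 features in infiltrated leaves of Col-0 and 21 mutant or insertion lines, 24 h after Psm in all lines, after water in Col-0 (LW03 and LW05) and coi1, and after the COR(-) strain in Col-0 and coi1 of LW05. Each group had 3 arrays, pbs3 2. Coronatine is a toxin of Psm that acts as a mimic of jasmonoyl-isoleucine, and COI1 is the receptor subunit that binds both. Levels are deposited log2 values as mean ± SD, and differences are log2 differences with their SE from limma. The Col-0 water array of LW05 set 1 had an r of at most 0.0253 with any other array, whereas arrays within the other groups had an r of at least 0.86. It was kept, and through the spread shared by all groups it also enters the SE and adjusted p of comparisons without its group. The values without this array are given beside the log2 differences in the text that it moved by over 1.5-fold or whose call it changed.

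The first question was how leaves of Col-0 respond to Psm. AT3G13950, which encodes an ankyrin-repeat protein, stood at 7.35 ± 0.71 (n = 6) after Psm and 2.09 ± 1.74 (n = 6) after water, a rise of 5.27 ± 0.36 (adjusted p = 4.51e-21). AT1G68620 rose by 5.25 ± 0.27 (38.1-fold) and CHI (AT2G43570), a chitinase-family gene, by 5.23 ± 0.29 (37.6-fold). GSTF3 (AT2G02930), a glutathione S-transferase, rose by 4.54 ± 0.50, and AT2G34810, of the berberine-bridge enzyme family, by 4.18 ± 0.38. AT5G60800 rose by 3.54 ± 0.38, AT4G33540 by 3.40 ± 0.21, and AT2G04400, an indole-3-glycerol-phosphate synthase of tryptophan synthesis, by 3.34 ± 0.30. All these rises were seen in 6 of 6 sets, which the rule for naming genes requires. Without the outlying water array AT3G13950 rose by 5.95 and GSTF3 by 3.80.

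The largest falls after Psm were those of AT3G16370 (-3.46 ± 0.35, adjusted p = 6.44e-14) and AT3G18050 (-2.71 ± 0.20). LHCB4.3, a light-harvesting protein of photosystem II, fell by 2.05 on the log2 scale, ATHM2, an m-type thioredoxin of the chloroplast, by 1.55, and COR47, a dehydrin, by 1.39. AT1G64710, AT2G04700, AT3G12390 and RAP changed by -1.44, -1.13, -1.11 and -1.06. UGT85A2 changed by -0.81 (adjusted p = 0.00984), a call that ended without the outlying water array (-0.22, adjusted p = 0.337).

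The SA-responsive and systemic acquired resistance list rose with infection, with 3 of 3 measured members raised (3 also adjusted over the list alone). GRX480 (AT1G28480), a glutaredoxin, rose by 3.69 ± 0.31, UGT76B1 (AT3G11340), a glucosyltransferase, by 3.51 ± 0.40, and the transcription factor gene WRKY53 by 2.02. The list's unadjusted fry p was 7.71e-23, and the unadjusted camera p was 0.0428 with an estimated correlation. Of the other list members, PDF1.2, a plant defensin, changed by -1.34 (adjusted p = 3.74e-05) and WRKY29 by -0.01 (adjusted p = 0.962; -0.78 with adjusted p = 0.000464 after median centring). WRKY22 stood 0.41 higher (adjusted p = 0.194), and 1.04 higher without the outlying array (adjusted p = 4.85e-07). The reference genes AT4G26410 and AT5G60390 differed by 0.27 and 0.02, and by -0.50 and -0.75 after median centring (adjusted p = 0.0359 and 0.000835).

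In all, 277 features rose (78 named) and 97 fell (27 named) with infection in Col-0. The direction of the smaller changes rests on the scale: the median of all features rose by 0.49 as deposited and changed by -0.28 after each array was centred on its median, where 175 features rose and 244 fell (177 and 243 after quantile normalization). Centring on the reference genes kept the balance, with a median of 0.35, 237 features raised and 102 lowered.

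Whether the response needs coronatine was asked with the COR(-) strain. In Col-0 it raised AT3G13950 by 5.2 ± 0.50 (n = 3 and 3, adjusted p = 1e-13), GSTF3 by 4.99 ± 0.71, CHI by 4.99 ± 0.41 and AT2G38870, a proteinase inhibitor, by 4.52 ± 0.48. AT3G16370 changed by -2.91, AT3G18050 by -2.76 and COR47 by -1.61. AT4G24350 changed by -1.97, and by -0.76 without the outlying array (adjusted p = 0.0665). Without that array the differences were 6.57 for AT3G13950, 3.52 for GSTF3, 3.81 for AT2G38870, -3.99 for AT3G16370 and -2.13 for AT3G18050, all still called. The 3 members of the SA-responsive list were raised: GRX480 by 1.51, UGT76B1 by 1.84 (2.65 without the outlying array) and WRKY53 by 1.74. The unadjusted fry p of the list was 5.11e-08 (camera p = 0.167 with an estimated correlation). In all 191 features rose and 109 fell, and 149 and 188 after median centring, 115 and 197 after centring on the reference genes, or 152 and 196 after quantile normalization. Without the outlying array 203 rose and 62 fell. The reference genes AT4G26410 and AT5G60390 themselves differed by 0.71 (adjusted p = 0.027) and 0.53 (adjusted p = 0.0907, and 0.0317 with the sets as a replicate block), and by 0.19 and 0.24 without that array.

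Psm set against the COR(-) strain in Col-0 of LW05 gives the part of the response that came with coronatine. AT3G59930, a defensin-like gene, stood at 6.18 ± 0.49 (n = 3) after Psm and 2.14 ± 0.56 (n = 3) after the COR(-) strain, a difference of 4.03 ± 0.70 (adjusted p = 8.75e-06). AT2G34810 was higher with coronatine by 3.88 ± 0.54 (14.7-fold, adjusted p = 1.38e-07), GRX480 by 2.65 ± 0.44 and AT1G68620 by 2.62 ± 0.38. UGT76E12, a glucosyltransferase gene, was higher by 2.54 ± 0.76, AT2G32150 by 2.5, AT1G10585, which encodes a bHLH protein, by 2.29, AT1G62660 by 2.14, AT4G24350 by 2.14 and AT2G18210 by 1.83. Lower with coronatine were AT5G52760 (-1.38 ± 0.33, adjusted p = 0.000876) and SAL2, of the SAL1 phosphatase family (-0.90 ± 0.30, adjusted p = 0.0249), 2 of the 5 features that fell. Each of these was seen in 3 of 3 sets, which the rule for naming genes requires.

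In the SA-responsive list GRX480 alone was called for coronatine. UGT76B1 differed by 0.73 (adjusted p = 0.455) and WRKY53 by -0.19 (adjusted p = 0.842). The fry test of the list gave an unadjusted p of 0.000587 (camera p = 0.271 with an estimated correlation). Coronatine raised 101 features (26 named) and lowered 5. The split was 63 to 34 after median centring, 55 to 42 after quantile normalization and 102 to 2 after centring on the reference genes. Without the Col-0 COR(-) array of set 3 the calls numbered 65.

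**Figure D1:**
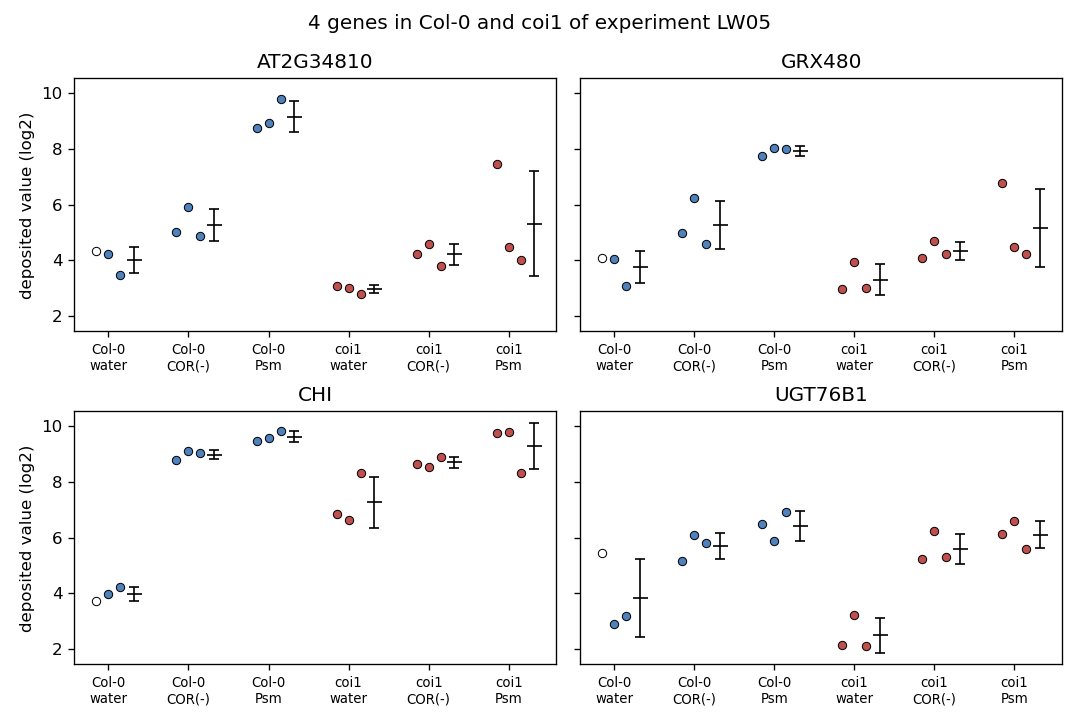
Deposited log2 value of AT2G34810, GRX480, CHI and UGT76B1 in each LW05 array of Col-0 (blue) and coi1 (red) after water, the COR(-) strain or Psm; bars show the mean and SD of 3 arrays, and the white circle is the outlying water array. AT2G34810 and GRX480 stand higher in Col-0 after Psm than after the COR(-) strain (3.88 and 2.65), and the coi1 Psm array of set 1 stands at 7.46 for AT2G34810 against 4.47 and 4.00 in sets 2 and 3.

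In coi1, Psm still raised AT3G13950 (4.29 ± 0.50, n = 3 and 3, adjusted p = 2.14e-10), AT1G68620 (3.96 ± 0.38), UGT76B1 (3.61 ± 0.56) and AT2G04400 (3.2 ± 0.42), and lowered AT3G16370 (-3.03 ± 0.49), TUB6, a beta-tubulin (-1.79), AT3G18050 (-1.53) and ATHM2 (-1.49). The COR(-) strain raised AT3G13950 by 4.13, AT3G28510, which encodes an AAA-type ATPase, by 3.35, UGT76B1 by 3.09 and AT1G68620 by 3.08, and AT3G16370, TUB6, AT3G18050 and ATHM2 changed by -2.88, -1.98, -1.5 and -1.46. WRKY22 rose by 1.26 with Psm and 1.2 with the COR(-) strain, WRKY53 by 1.23 and 1.62, and GRX480 by 1.84 with Psm. GRX480 was not called with the COR(-) strain, where 2 of the 3 members of the SA-responsive list were raised. After median centring the calls of WRKY22 ended (0.84, adjusted p = 0.0586, and 0.86, adjusted p = 0.0528), and so did that of WRKY53 with Psm (0.81, adjusted p = 0.0693). Without the coi1 Psm array of set 1 the Psm calls of GRX480 (1.04, adjusted p = 0.0643), WRKY22 (0.94, adjusted p = 0.087) and WRKY53 (0.99, adjusted p = 0.0559) ended. The fry test of the SA-responsive list gave an unadjusted p of 2.01e-10 for Psm (camera p = 0.0613 with an estimated correlation). For the COR(-) strain the fry p was 1.15e-08 (camera p = 0.0842 with an estimated correlation). Psm raised 176 and lowered 49 features in coi1 (120 and 86 after median centring, 120 and 126 after quantile normalization), and the COR(-) strain raised 164 and lowered 43 (122 and 73, or 120 and 110).

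The effect of coronatine within coi1 passed the threshold in limma for 0 features, with 15 at an unadjusted p under 0.05. AT2G34810 differed by 1.09 ± 0.54 (adjusted p = 0.998), AT3G59930 by 1.33 ± 0.70 and GRX480 by 0.82 ± 0.44, and without the coi1 Psm array of set 1 by 0.02, 0.07 and 0.02. The difference of this effect between Col-0 and coi1, tested directly, was called for AT2G34810, larger in Col-0 by 2.79 ± 0.76 (adjusted p = 0.0359; 2.52 with adjusted p = 0.0549 after median centring), and for GRX480 it was 1.83 ± 0.63 (adjusted p = 0.142, and 0.0413 with the sets as a replicate block). Without that array it was 3.86 (adjusted p = 0.000135) and 2.64 (adjusted p = 0.0023). In all 8 features showed a larger effect in Col-0 and 0 a smaller one. This count was 27 with the sets as a replicate block, 19 without the outlying water array, 2 after median centring, 108 with array quality weights, 0 with the LW05 arrays alone, and 0 to 43 when 1 array of the groups compared was left out. The coi1 Psm array of set 1, at 7.46 for AT2G34810 where sets 2 and 3 had 4.47 and 4.00, gave the 43 when left out.

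Leaves of coi1 and Col-0 also differed after water. CHI stood at 7.26 ± 0.91 (n = 3) in coi1 and 3.98 ± 0.26 (n = 3) in Col-0, a difference of 3.28 ± 0.41 (adjusted p = 1.5e-08). BIP1, an endoplasmic reticulum chaperone, was higher in coi1 by 2.0 ± 0.36, AT1G76960 by 1.86 ± 0.42 and WRKY53 by 1.04 (adjusted p = 0.0303; 1.17 with adjusted p = 0.0736 without the outlying array). AT1G62660 was lower by 1.84 on the log2 scale (-1.84) and APS3, an ATP sulfurylase, by 1.26 (-1.26). GSTF3 (2.51), AT2G18680 (-1.99), PDF1.2 (-1.87) and WRKY22 (-1.35) lost their calls without the outlying array (1.04, -0.28, -1.16 and -0.08). The fry test of the SA-responsive list gave an unadjusted p of 0.695 (camera p = 0.985 with an estimated correlation). In all 72 features were higher and 99 lower, 31 and 15 without that array (33 calls kept), and 34 and 118 after centring on the reference genes. Leaving out the Col-0 water array of set 2 gave 259 calls, and leaving out the coi1 water array of set 3 gave 93.

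The infection response differed between coi1 and Col-0 of LW05 when tested directly. The rise of CHI was smaller in coi1 by 3.61 on the log2 scale (-3.61 ± 0.58, adjusted p = 1.05e-05), and that of GRX480 differed by -2.32 ± 0.63 (adjusted p = 0.00675). For CHI this came mostly with the level after water, at 6.85, 6.64 and 8.31 in coi1 and 3.73, 3.97 and 4.24 in Col-0. After Psm CHI stood at 9.75, 9.77 and 8.33 in coi1 and 9.45, 9.58 and 9.82 in Col-0. The differences for AT2G25450 (-3.08 ± 0.86), GSTF3 (-2.96 ± 1.00) and AT2G32150 (-2.91 ± 0.73) were called, but not without the outlying array (-1.42, -1.49 and -1.66). The same held for ATPMEPCRB, a pectin methylesterase (1.77 ± 0.59, then 0.34), WRKY22 (1.65 ± 0.56, then 0.39), AT3G18050 (1.40 ± 0.40, then 0.77) and AT2G26190 (0.73 ± 0.24, then 0.53). In all the difference, coi1 minus Col-0, was above 0 for 18 called features and below 0 for 67, 64 and 51 after median centring, 57 and 53 after quantile normalization, and 38 and 96 with the sets as a replicate block. Without the outlying array it was above 0 for 3 and below 0 for 62, and 40 calls were kept. The count of 85 became 195 or 180 without the Col-0 water array of set 2 or 3, and 52 without the coi1 Psm array of set 3.

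Each genotype was next compared with Col-0 24 h after Psm. Lines other than coi1 had no water arrays. For them a difference present before infection cannot be told from a changed response to it. After Psm, coi1 had lower levels of AT2G34810 (6.06 ± 1.58, n = 6) than Col-0 (9.26 ± 0.40, n = 6), a difference of -3.2 ± 0.38 (adjusted p = 2.74e-10). GRX480 differed by -3.01 ± 0.31, UGT76E12 by -2.85 ± 0.54, AT1G10585 by -2.23 ± 0.39 and AT2G32150 by -2.0 ± 0.37. AT4G24350 (-1.90), AT2G18210 (-1.82), AT1G68620 (-1.64), AT1G62660 (-1.53) and AT2G25450 (-1.39) were also lower. Higher in coi1 were AT5G52760 (0.97 ± 0.23), SAL2 (0.91 ± 0.21), EXO (0.85 ± 0.28), WRKY53 (0.85 ± 0.27), LHCB4.3 (0.82 ± 0.25) and AT2G39710 (0.69 ± 0.22), each in 6 of 6 sets, as the naming rule requires. Of the SA-responsive list GRX480 was lower, WRKY53 higher and UGT76B1 at -0.56 (adjusted p = 0.357). The fry test gave an unadjusted p of 7.31e-05 (camera p = 0.382 with an estimated correlation). In all 35 features were higher and 126 lower, 75 and 93 after median centring, and 82 and 93 after quantile normalization. The effects of coi1 in LW02 and LW05 had an r of 0.818 across the 576 features, which are not independent replicates.

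**Figure D2:**
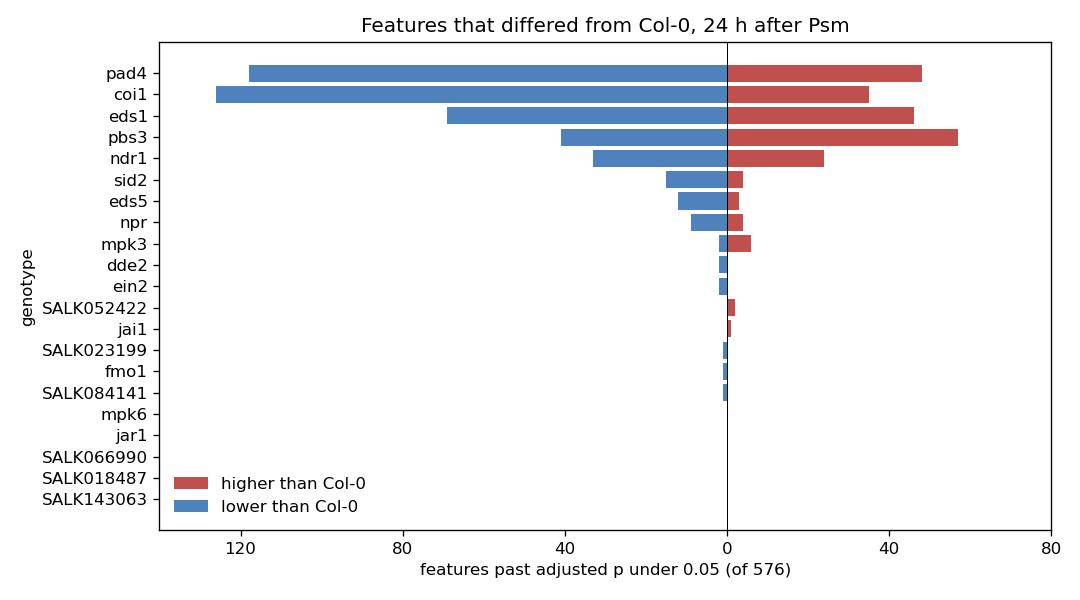
Number of the 576 features that were higher (red) or lower (blue) than in Col-0 of the same experiment 24 h after Psm, at an adjusted p under 0.05, for 21 genotypes. The counts run from 166 in pad4 and 161 in coi1 to 0 in mpk6, jar1, SALK066990, SALK018487 and SALK143063; coi1 has 6 arrays and pbs3 2, against 3 for the others.

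The JA-related lines and ein2 were measured in LW02. In dde2, which lacks an enzyme of JA synthesis, COR47 was lower (4.44 ± 0.23 against 6.56 ± 0.25, n = 3 each, a difference of -2.11 ± 0.48, adjusted p = 0.0131), 1 of the 2 features called. In jai1, PDF1.2 was higher (5.31 ± 1.12 against 2.62 ± 0.14, n = 3 each, a difference of 2.69 ± 0.41, adjusted p = 3.89e-06). It was the 1 feature called, with 2 under the replicate block and 2 without the outlying water array. In jar1 no feature passed in limma, with 12 at an unadjusted p under 0.05. In ein2, an ethylene-insensitive mutant, 2 features without a gene name were lower. The ein2 count was 16 with the sets as a replicate block, 10 without the outlying array, 7 after median centring (1 higher and 6 lower) and 4 after quantile normalization (1 and 3). With array quality weights dde2 had 34, ein2 55, jai1 15 and jar1 0 calls. In dde2, 1 call was left without the arrays of Col-0 or dde2 from set 1 or 3, and in ein2 without those of set 1 or Col-0 of set 3.

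The lines dde2, jar1 and jai1 were also set directly against coi1 of LW02, whose arrays enter the coi1 effect above as well. GRX480 was higher in dde2 than in coi1 by 3.95 ± 0.44 (adjusted p = 3.66e-10), in jar1 by 3.37 ± 0.44 and in jai1 by 3.6 ± 0.44. AT3G59930 was higher by 3.35, 3.93 and 4.60, and UGT76E12 by 3.15, 3.11 and 2.88. AT1G10585 was higher by 3.18 in dde2 and 2.40 in jar1, and AT2G34810 by 2.95 in jai1. WRKY53 was lower than in coi1 by 1.68, 1.42 and 1.38 on the log2 scale (-1.68, -1.42 and -1.38). AT5G64120, a peroxidase, was lower in dde2 (-1.81) and jai1 (-1.71), COR47 and AT1G05340 in dde2 (-2.36 and -1.78), AT5G52760 and AT2G26190 in jar1 (-1.23 and -0.48), SAL2 in jar1 and jai1 (-0.92 and -1.24) and AT2G38870 in jai1 (-1.42). PDF1.2 was higher in jai1 than in coi1 by 2.64. UGT76B1 was higher in dde2 than in coi1 by 1.97. For dde2, jar1 and jai1 the fry tests of the SA-responsive list gave unadjusted p = 5.34e-05, 0.00199 and 0.000461 (camera p = 0.169, 0.272 and 0.148 with an estimated correlation).

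In dde2 86 features were higher and 41 lower than in coi1 (68 and 60 after quantile normalization). In jar1 there were 72 and 15 (55 and 27 after median centring, 58 and 30 after quantile normalization), and in jai1 60 and 23 (46 and 35, 47 and 29, and 126 in all with the sets as a replicate block). Without the coi1 array of set 1 the totals were 72, 42 and 18. The jai1 total was also 47 without the coi1 or jai1 array of set 3, and 50 without the jai1 array of set 1.

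The SA branch was followed in sid2 and eds5, which are blocked in SA accumulation, and npr, all in LW01. UGT76B1 stood at 4.45 ± 1.02 in sid2 and 5.09 ± 0.97 in eds5 against 7.38 ± 1.00 in Col-0 (n = 3 each), differences of -2.93 ± 0.56 (adjusted p = 0.000144) and -2.29 ± 0.56 (adjusted p = 0.00671). AT3G28510 was lower in sid2 (-2.33 ± 0.42), eds5 (-2.28 ± 0.42) and npr (-2.06 ± 0.42), and so was AT3G51330, an aspartyl protease gene (-1.02, -1.35 and -0.97). UGT76B1 in npr differed by -1.76 ± 0.56 (adjusted p = 0.0836, 0.0329 without the outlying water array and 0.00608 with the sets as a replicate block). Higher than Col-0 were AT4G24340 (1.29) and AT5G21105 (0.99) in sid2, AT4G17470 in eds5 (1.88) and AT5G21105 in npr (1.52). The SA-responsive list was lower in all 3, with unadjusted fry p = 8.14e-05, 0.000344 and 0.00952 (camera p = 0.00204, 0.00373 and 0.0408 with an estimated correlation). UGT76B1 was the member called in sid2 and eds5, and no member was called in npr, where 1 was called adjusted over the list alone. The 3 comparisons share the Col-0 arrays, so part of what they have in common may come from those arrays.

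In sid2 4 features were higher and 15 lower, in eds5 3 and 12 (8 and 12 after median centring, 3 and 3 after centring on the reference genes), and in npr 4 and 9 (7 and 10 after median centring). The totals of 19, 15 and 13 became 29, 26 and 24 with the sets as a replicate block and 29, 29 and 27 without the outlying water array. Without the Col-0 array of set 3 sid2 had 12 and eds5 8 calls, and npr had 22 without the Col-0 array of set 2 and 8 without its own array of set 3. Set directly against sid2, AT4G17470 was higher in eds5 by 1.5 ± 0.36 (adjusted p = 0.0271), 1 of 2 features called, and 1 when any single eds5 or sid2 array was left out. Between npr and sid2 1 feature without a gene name was called, and 3 with the replicate block.

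Loss of PAD4, a regulator of defence upstream of SA, changed more genes. AT4G17470 stood at 7.25 ± 0.93 in pad4 and 3.23 ± 0.27 in Col-0 (n = 3 each), a difference of 4.02 ± 0.36 (adjusted p = 4.37e-14). AT3G28270 was higher by 3.02 ± 0.42, AT1G54010 by 2.75 ± 0.36 and UGT84A3, a glucosyltransferase, by 2.12 ± 0.27. GSTF3 (-2.96 ± 0.71), CHI (-2.67 ± 0.41), UGT76B1 (-2.57 ± 0.56), AT5G39670, which encodes a calcium-binding protein (-2.17 ± 0.58), GRX480 (-1.18 ± 0.44) and AT2G04400 (-1.07) were lower. The calls of GRX480 and AT2G04400 ended after median centring (-0.91, adjusted p = 0.0976, and -0.79, adjusted p = 0.135). The fry test of the SA-responsive list, 2 of whose 3 members were lower, gave an unadjusted p of 0.000185 (camera p = 0.198 with an estimated correlation). Directly compared with sid2, pad4 had more AT4G17470 (3.65), AT3G28270 (2.79), AT1G54010 (2.38) and UGT84A3 (1.62), and less AT1G26380, of the berberine-bridge enzyme family (-3.19), GSTF3 (-2.97), AT3G54150 (-2.52) and CHI (-2.44).

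In pad4 48 features were higher and 118 lower than in Col-0, 74 and 73 after median centring, 60 and 62 after centring on the reference genes, and 57 and 66 after quantile normalization. Without the Col-0 array of set 3 the total was 106. Against sid2, 29 features were higher and 85 lower (43 and 60 after median centring, 37 and 53 after quantile normalization), and 73 in all without the pad4 array of set 2. Of the 277 features raised by infection, 107 were lower in pad4, 14 in sid2, 11 in eds5 and 8 in npr.

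In eds1 of LW03, which lacks the partner protein of PAD4, AT4G17470 was higher than in Col-0 by 5.32 ± 0.36 (8.72 ± 0.17 against 3.40 ± 0.34, n = 3 each, adjusted p = 7.51e-20). AT1G54010 was higher by 4.50 ± 0.36, AT4G24350 by 2.94 ± 0.43, AT3G28270 by 2.17 ± 0.42 and PDF1.2 by 1.5. Hsp70-2, a chaperone (-2.54 ± 0.48), CHI (-2.51 ± 0.41), AT3G13950 (-2.42 ± 0.50) and AT3G28510 (-2.21 ± 0.42) were lower. UGT76B1 differed by 0.05 ± 0.56 (adjusted p = 0.977). In all 46 features were higher and 69 lower (58 and 56 after quantile normalization). Tested directly, the difference from Col-0 in eds1 exceeded that in pad4 for AT4G24350 by 2.56 ± 0.61 (adjusted p = 0.0181) and for UGT76B1 by 2.63 ± 0.79 (adjusted p = 0.0768, 0.0287 without the outlying water array and 0.00466 with the sets as a replicate block). The SA-responsive list had an unadjusted fry p of 0.0041 for the difference between eds1 and pad4 (camera p = 0.0349 with an estimated correlation). For this difference 4 features were called, 21 with the sets as a replicate block, 20 without the outlying water array, 7 after median centring (3 and 4), and 0 to 20 when 1 array was left out.

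**Figure D3:**
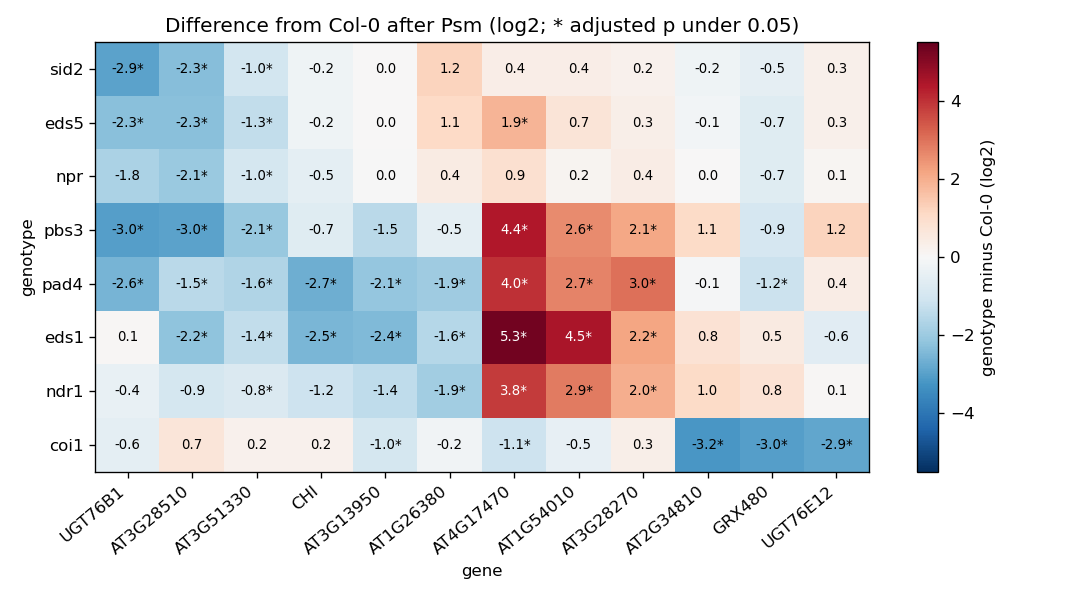
Difference from Col-0 (log2) of 12 genes, chosen after their values were seen, in 8 genotypes 24 h after Psm; an asterisk marks an adjusted p under 0.05 over all 576 features. AT4G17470 is higher in pbs3, pad4, eds1 and ndr1 (4.39, 4.02, 5.32 and 3.83), while AT2G34810, GRX480 and UGT76E12 are lower in coi1 (-3.2, -3.01 and -2.85).

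In ndr1 of LW05, AT4G17470 was higher by 3.83 ± 0.36 (8.13 ± 0.11 against 4.31 ± 0.50, n = 3 each, adjusted p = 3.64e-13), AT1G54010 by 2.87 ± 0.36, AT3G28270 by 2.0 ± 0.42 and GTR1, a glucosinolate transporter gene, by 1.55 ± 0.50. AT1G26380 (-1.93 ± 0.47) and BIP1 (-1.39 ± 0.36; -0.78 with adjusted p = 0.235 after quantile normalization) were lower, and so were UGT74B1 (-1.14) and AT3G51330 (-0.79), whose calls ended after median centring (-1.02, adjusted p = 0.0965, and -0.66, adjusted p = 0.0631). In all 24 features were higher and 33 lower (28 and 22 after median centring, 18 and 16 after centring on the reference genes). The total of 57 was 106 with the sets as a replicate block and 89 without the outlying water array, and it was 33, 27, 35 and 35 without ndr1 array 1, ndr1 array 2, Col-0 array 2 or Col-0 array 3.

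In pbs3 of LW05, which lacks an enzyme of SA accumulation, AT3G59930 stood at 11.0 ± 0.72 (n = 2) against 6.18 ± 0.49 (n = 3) in Col-0, a difference of 4.82 ± 0.79 (adjusted p = 1.62e-06). AT4G17470 was higher by 4.39 ± 0.40, AT4G24340 by 3.25 ± 0.43 and AT1G54010 by 2.6 ± 0.41. UGT76B1 (-3.05 ± 0.63), AT3G28510 (-2.96 ± 0.47), GSTF3 (-2.32 ± 0.79) and AT3G51330 (-2.07 ± 0.27) were lower. The fry test of the SA-responsive list gave an unadjusted p of 6.57e-06 (camera p = 0.0155 with an estimated correlation). In all 57 features were higher and 41 lower, and 75 and 22 after centring on the reference genes. With either pbs3 array left out, 49 or 57 were called.

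The mitogen-activated protein kinase mutants were measured in LW01. In mpk3, AT4G27280 was higher (6.09 ± 0.50 against 4.54 ± 0.20, n = 3 each, a difference of 1.55 ± 0.41, adjusted p = 0.0403) and so was AT5G52760 (1.19 ± 0.33, adjusted p = 0.0412), 2 of 6 features higher and 2 lower (3 and 0 after centring on the reference genes). This total of 8 was 18 with the sets as a replicate block, and 0, 4, 2 and 0 without mpk3 array 1, mpk3 array 2, mpk3 array 3 or Col-0 array 2. In mpk6 no feature passed in limma, with 6 at an unadjusted p under 0.05, and between mpk3 and mpk6 none passed, with 29 at an unadjusted p under 0.05 and 1 called with the replicate block.

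In fmo1 of LW03 a single feature was called, feature 45, which has no gene name here and was lower by 5.61 on the log2 scale (-5.61 ± 0.48, adjusted p = 3.89e-15). The genes hit in the 6 SALK insertion lines are not given in the sources used here. In SALK052422 AT1G54010 (1.5 ± 0.36) and AT4G17470 (1.45 ± 0.36) were higher (adjusted p = 0.0448 for both), 2 calls that ended without Col-0 array 1, 2 or 3 or SALK052422 array 2 or 3, and that became 4 with the replicate block. In SALK023199 and SALK084141 1 feature without a gene name was lower. In SALK066990, SALK018487 and SALK143063 no feature passed in limma, with 1, 1 and 12 at an unadjusted p under 0.05.

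Genotypes of different experiments, which share no array, were compared by the correlation of their effects across the 576 features. Over 177 pairs r ran from -0.508 to 0.818 with a median of -0.016, and features are not independent replicates, so no p is given. The effect of eds1 had an r of 0.792 with ndr1, pad4 an r of 0.791 with ndr1 and 0.775 with eds1, and pbs3 an r of 0.712 with pad4, 0.663 with eds5 and 0.521 with sid2. AT4G17470, AT1G54010, AT3G28270, AT5G21105 and GTR1 were among the 29 features higher in both pad4 and eds1, where independent lists would share 3.83.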

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

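The direct tests of a difference between coi1 and Col-0 were fixed before the data were examined, and the tests of explanations below were chosen after the results were seen. The effect of coronatine differed between Col-0 and coi1 in 8 features, among them AT2G34810 (2.787). The response to Psm differed between coi1 and Col-0 in 85 features. Among the named genes it was larger in coi1, or fell less, for ATPMEPCRB (1.772), WRKY22 (1.65), AT3G18050 (1.4) and AT2G26190 (0.732), and smaller for CHI (-3.614), AT2G25450 (-3.079), GSTF3 (-2.96), AT2G32150 (-2.906) and GRX480 (-2.321). The smaller rise of CHI came mostly with its higher level in coi1 after water. Without the Col-0 water array of LW05 set 1, the calls of CHI and GRX480 (-2.496, adjusted p = 0.00818) held and the others ended.

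That array is the first pattern. It correlated with no other array, with an r between -0.0516 and 0.0253, so it was not an intact array of another group under a wrong label. No shift of its rows by a constant number, forwards or in reverse order, restored the match (highest r 0.137 over 1152 tries). Its values as a set were as close to those of another array (Kolmogorov-Smirnov distance 0.066) as arrays of one group are to each other (up to 0.127), but no closer than 0.156 to the other 8 water arrays, so the values of a sample unlike these water arrays, in another feature order, may be the cause. It also held 230 distinct values against 296 to 454 in the other arrays, as a weak or failed hybridisation could give. Another feature order alone leaves the number of distinct values unchanged, so it does not explain the 230. Both explanations stay open. No biological explanation was tested.

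The second pattern is the coi1 Psm array of set 1 in LW05, which lies between coi1 and Col-0. Over the 64 features lower in coi1 in LW02, it stood at a median of -0.682 from the Col-0 mean, against -2.188 and -2.334 in sets 2 and 3, so it was not a Col-0 array under a coi1 label. The Col-0 array of that set stood at -0.104, which argues against a swap, and the features without a coi1 call in LW02 were shifted by a median of 0.0994, which argues against a change of scale over the whole array. Of the 64 features, 93.8% lay nearer to Col-0 than in the other coi1 arrays, so leaves of Col-0-like plants in the sample may be the cause, and a weaker coi1 effect in those plants was not tested. The coi1 Psm array of set 2 in LW02 also stood nearer to Col-0 (-0.713 against -1.836 and -1.478 over 83 features), and without the LW05 array the coronatine by coi1 interaction had 43 calls.

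The third pattern is that features lower in pbs3 changed less in eds1 than in pad4. Over these 41 features, from arrays of another experiment, the median was -1.692 in pbs3, -1.301 in pad4 and -0.593 in eds1, and the difference between eds1 and pad4 had a median of 0.714 (0.121 over all features) and was above 0 for 36. Their median response to infection was 2.22 in LW03, where eds1 was measured, and 2.088 in LW05 (ratio 1.06). The LW05 value includes the outlying water array, and the ratio was not taken without it. The eds1 arrays differed from Col-0 in 115 features where the highest other split of these arrays gave 1. Thus neither a response missing in LW03 nor wild-type arrays under an eds1 label accounts for the pattern. LW01, where pad4 was measured, has no water arrays, so a larger response of these features in LW01 could not be tested. A smaller need for EDS1 than for PAD4 in the level of these features after Psm may explain it. Over all features, however, this difference had 4 calls, and 0 to 20 with 1 array left out. It stays a hypothesis found on these data. A difference between experiments LW01 and LW03 stays open and untested. So does a strain variant, since the background accession of eds1 was not given in the labels used here.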

How the results depend on the processing

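Fits without the outlying water array in every comparison, alone or with the replicate block, were chosen after the data were seen, and so were the tests on other splits, while the other alternatives were fixed before. Of the 198 named calls tested under each setting none changed direction. All were called in these same data, and the naming rule requires the same direction in every set for the largest changes. This left little room for a reversal, so its absence is weak evidence. With the replicate block 198 of 198 stayed past the threshold, with median centring 188, with the reference genes 163, with quantile normalization 178, with array weights 188 and with the arrays of the experiments in the contrast alone 167. Without the dimmest 25% of features 158 of 159 stayed, and leaving out 1 array kept 1313 of 1480. The cause of the changes below was not tested, apart from what the model itself fixes. Fewer arrays enter a fit that leaves arrays out. All groups share 1 estimate of each feature's spread, so the outlying water array also enters comparisons without its group. Without it their log2 differences stayed the same while calls were added, as in ndr1 (57 to 89) and ein2 (2 to 10). For AT4G40030 in pad4 the difference was 0.998 in both fits, and the adjusted p fell from 0.145 to 0.000355. The plan to add 50 before taking logs applied to linear values and was not run. Array signal over background was not used, and the 3 arrays per group limit what can be called.

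With the replicate block, 14 of 38 counts moved by over 1.5 times: coronatine by coi1 interaction 8 to 27, infection by coi1 interaction 85 to 134, eds5 15 to 26, mpk3 8 to 18, npr 13 to 24, sid2 19 to 29, ein2 2 to 16, jai1 1 to 2, SALK052422 2 to 4, ndr1 57 to 106, npr minus sid2 1 to 3, mpk3 minus mpk6 0 to 1, jai1 minus coi1 83 to 126 and eds1 minus pad4 4 to 21. The replicate block ended none of the 198 named calls. It took values given above as not called past the threshold: GRX480 in the coronatine by coi1 interaction (adjusted p = 0.0413), UGT76B1 in npr (0.00608) and in eds1 minus pad4 (0.00466), and AT5G60390 with the COR(-) strain in Col-0 (0.0317).

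With the block and without the outlying water array, the counts were coronatine in Col-0 184, coronatine by coi1 interaction 72, coi1 minus Col-0 after water 81, coi1 243, eds5 42, mpk3 23, npr 46, pad4 257, sid2 43, dde2 4, ein2 23, jai1 6, eds1 211, SALK052422 8, SALK084141 2, ndr1 152, pbs3 176, npr minus sid2 4, pad4 minus sid2 207, mpk3 minus mpk6 15, dde2 minus coi1 217, jar1 minus coi1 158, jai1 minus coi1 163 and eds1 minus pad4 55.

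Centring on the median gave coronatine by coi1 interaction 2, ein2 7 and eds1 minus pad4 7. Centring on the reference genes gave coronatine by coi1 interaction 3, infection by coi1 interaction 48, eds5 6, mpk3 3, npr 5, sid2 8, SALK052422 0, ndr1 34 and eds1 minus pad4 0. Quantile normalization gave coronatine by coi1 interaction 1, mpk3 0, ein2 4 and eds5 minus sid2 1. Without the dimmest 25% of features, coronatine by coi1 interaction had 17, coi1 minus Col-0 after water 108, jai1 0 and SALK052422 0. A minimum of 2-fold gave coi1 92, and 0 infection-raised features lower in mpk3 in place of 2. Fry called the SA-responsive list in 15 comparisons and camera with an estimated correlation in 7, 6 of them shared and npr minus sid2 by camera alone (adjusted p = 0.0458, fry 0.129).

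Array weights gave coronatine in Col-0 196, coronatine by coi1 interaction 108, coi1 minus Col-0 after water 71, infection by coi1 interaction 139, eds5 34, npr 26, sid2 38, dde2 34, ein2 55, jai1 15, SALK023199 3, eds1 228, SALK052422 17, SALK143063 2, ndr1 103, npr minus sid2 2, jai1 minus coi1 133 and eds1 minus pad4 32. With the arrays of the experiments in the contrast alone, the counts were COR(-) strain in Col-0 180, coronatine in Col-0 62, coronatine by coi1 interaction 0, coi1 minus Col-0 after water 27, infection by coi1 interaction 22, eds5 24, mpk3 1, npr 22, dde2 4, ein2 17, jai1 3, SALK052422 5, ndr1 15, pbs3 43, eds5 minus sid2 1, jar1 minus coi1 135, jai1 minus coi1 129 and eds1 minus pad4 14.

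Leaving out 1 array gave 65 to 139 for coronatine in Col-0, 0 to 43 for coronatine by coi1 interaction, 46 to 259 for coi1 minus Col-0 after water, 52 to 195 for infection by coi1 interaction, 8 to 29 for eds5, 0 to 10 for mpk3, 8 to 27 for npr, 106 to 195 for pad4, 12 to 29 for sid2, 1 to 3 for dde2, 1 to 10 for ein2, 1 to 2 for jai1, 0 to 3 for SALK052422, 27 to 89 for ndr1, 49 to 131 for pbs3, 1 to 2 for eds5 minus sid2, 73 to 150 for pad4 minus sid2, 72 to 157 for dde2 minus coi1, 42 to 110 for jar1 minus coi1, 18 to 112 for jai1 minus coi1 and 0 to 20 for eds1 minus pad4. Where pbs3 was left with 1 array, that array is assumed to vary like the other groups.

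Other splits of the same arrays were counted. Where a comparison joins 2 pairs of groups (strata), 100 were drawn of the 200 splits that exchange arrays inside each stratum, the real one included. The highest count may thus lie among splits that were not drawn. For infection in Col-0, 1 of 100 splits, the real one, gave 374 calls (highest other 361), and for coi1 1 of 100 gave 161 (142). These small shares make chance unlikely for both but do not exclude it. Larger shares were found for the coronatine by coi1 interaction (26 of 100 splits gave at least 8, highest other 89), the infection by coi1 interaction (14 of 100, 85 against 144) and eds1 minus pad4 (29 of 100, 4 against 218), so chance cannot be excluded there. Splits far above the real count point to a structure of the samples: exchanging the genotypes in 1 stratum turns a difference of 2 effects into their sum. The splits of these 3 thus hold real genotype effects and are no measure of chance alone. Of the 32 splits that part every set, without and with the set as a replicate block, the real one alone reached its count for infection in Col-0 (374, highest other 358, and 408, 401) and coi1 (161, 142, and 197, 174). For the coronatine by coi1 interaction 10 splits did (8, 68) and 11 with the block (27, 111), for the infection by coi1 interaction 7 (85, 151) and 10 (134, 230), and for eds1 minus pad4 14 (4, 218) and 13 (21, 254).

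The pbs3 comparison, with 2 pbs3 arrays, was not split. The other comparisons allow 10 splits, too few for a share under 0.05. The real split alone reached its count (1 of 10) for the COR(-) strain in Col-0 (300, highest other 271), infection in coi1 (225, 19), the COR(-) strain in coi1 (207, 6), coronatine in Col-0 (106, 28), eds5 (15, 8), mpk3 (8, 5), npr (13, 6), pad4 (166, 29), sid2 (19, 7), dde2 (2, 0), ein2 (2, 0), jai1 (1, 0), SALK023199 (1, 0), eds1 (115, 1), SALK084141 (1, 0), ndr1 (57, 2), eds5 minus sid2 (2, 0), pad4 minus sid2 (114, 5), dde2 minus coi1 (127, 14), jar1 minus coi1 (87, 19) and jai1 minus coi1 (83, 10). The count was reached in 3 of 10 for coi1 minus Col-0 after water (171, 202), 2 of 10 for fmo1 (1, 5) and npr minus sid2 (1, 2), and 4 of 10 for SALK052422 (2, 7). A count of 0 is reached by 10 of 10 for coronatine in coi1 (0, 1), mpk6 (0, 4), jar1 (0, 1), SALK066990 (0, 0), SALK018487 (0, 0), SALK143063 (0, 0) and mpk3 minus mpk6 (0, 1). Among the 4 splits that part every set, the highest other was 271 for the COR(-) strain in Col-0 and 179 for coi1 minus Col-0 after water, both with the outlying array, and at most 10 elsewhere.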

Other observations

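The gene families below were chosen after their values were seen, and so were the tests of the 3 hypotheses, while the comparisons and scalings were fixed before. Of 5 chaperone genes, 4 rose with infection in Col-0: Hsp70-2 by 3.02 ± 0.34 (adjusted p = 3.87e-12), BIP1 by 2.99 ± 0.25, AT3G09440 by 1.87 ± 0.24 and AT2G29500, a small heat shock protein, by 1.46 ± 0.30. These 4 calls held after centring on the median (2.25, 2.22, 1.1 and 0.69), on the reference genes and after quantile normalization, while AT5G48570 stood at -0.07 (adjusted p = 0.887). In eds1, Hsp70-2 (-2.54) and AT3G09440 (-0.98, adjusted p = 0.0317) were lower, the latter not after centring on the median (-0.88, adjusted p = 0.0772), on the reference genes or after quantile normalization. AT2G29500 was lower in pad4 (-1.27, adjusted p = 0.0175, and -0.99, adjusted p = 0.064, after centring on the median), and BIP1 in ndr1 (-1.39, adjusted p = 0.00633, and -0.78, adjusted p = 0.235, after quantile normalization). AT5G48570 went the other way, higher in pbs3 (2.03, adjusted p = 0.0123), a call that held under the same 3 scalings. A difference among the 4 genes that rose with infection was not tested. WRKY6 rose by 2.55 ± 0.29 with infection and was lower in eds1 (-1.52, adjusted p = 0.0038, and -1.41, adjusted p = 0.0502, after centring on the reference genes) and in pad4 (-1.08, adjusted p = 0.0406, and -0.80, adjusted p = 0.11, after centring on the median).

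Of the chitinase genes other than CHI, AT2G43620 rose by 1.09 ± 0.30 and AT4G01700 by 0.62 ± 0.23 with infection, but both calls ended after centring on the median (0.32 and -0.15) and after quantile normalization (0.29 and -0.15), where the sign of AT4G01700 flips. The histone H3 genes AT1G09200, AT4G40030 and AT5G65360 were not called as deposited (-0.26, -0.39 and -0.01), and were called lower after centring on the median (-1.03, -1.17 and -0.79) and quantile normalization (-1.09, -1.36 and -1.09), but not after centring on the reference genes (-0.40, -0.54 and -0.16). Without the outlying water array AT4G40030 (-1.31, adjusted p = 3.2e-10) and AT5G65360 (-0.62, adjusted p = 0.0093) were called lower on the deposited scale, and AT1G09200 was not (-0.37, adjusted p = 0.058). The sugar-transferase gene UGT84A3 was higher in pad4 (2.12), eds1 (0.94) and pbs3 (0.85), calls that held under each of the 3 scalings.

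The first hypothesis was that coronatine acts on the genes it raises through COI1. The 101 features raised by coronatine in LW05 held 53 of the 64 features lower in coi1 in LW02, from other arrays, where independent lists would share 11.2, a ratio of 4.72. AT2G34810, AT3G59930, GRX480, UGT76E12 and GTR1 were among them. Independence is a low bar, since the 101 also held 69 of the 228 features raised by infection in LW03, where 40 would be shared, a ratio of 1.73. Action through COI1 could give this overlap, but the direct test of the difference between Col-0 and coi1 called 8 features. That count was 0 with the LW05 arrays alone, 108 with array quality weights and 43 without the coi1 Psm array of LW05 set 1. It thus does not settle the question.

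The second hypothesis was that coronatine-responsive genes rise where EDS1 is lost. The 46 features higher in eds1 (LW03) held 22 of the coronatine-raised features (LW05), where independent lists would share 8.07, a ratio of 2.73. AT3G59930, AT4G17470, AT4G24340, AT4G24350, AT1G62660, AT5G21105 and GTR1 were among them, whereas AT2G34810 and GRX480 differed by 0.78 (adjusted p = 0.358) and 0.49 (adjusted p = 0.524) in eds1. The 48 features higher in pad4 held 14, where 8.42 would be shared, but the 118 lower in pad4 held 31, where 20.7 would be shared (ratios of 1.66 and 1.5). The 69 features lower in eds1 held 13, where 12.1 would be shared. All 7 named features shared by eds1 and the coronatine-raised list were also higher in pbs3. AT4G17470, AT5G21105 and GTR1 were also higher in ndr1, so these rises were not particular to eds1. A part of the coronatine-responsive genes may thus be held down in a way that depends on EDS1, but not on EDS1 alone. A strain variant in the eds1 line was not tested.

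The third hypothesis was that a branch of the infection response needs both SID2 and PBS3. The 41 features lower in pbs3 (LW05) held 12 of the 15 features lower in sid2 (LW01), where independent lists would share 1.07, a ratio of 11.2, with UGT76B1, AT3G28510 and AT3G51330 among them. None of the 15 was raised by coronatine, but independent lists would share only 2.63, too few to draw a conclusion. The overlap of the sid2 and pbs3 lists could come from 1 branch that depends on both genes, and the features were not tested for a direct regulator. Neither line had water arrays, so a difference present before infection cannot be told from a changed infection response.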
